A study of Saccharomyces cerevisiae with 30 samples.

How the data were processed

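Ribosome profiling and poly(A) RNA sequencing of fractionated Saccharomyces cerevisiae were analysed from the deposited tables alone. Per the labels, cells grew in rich medium to mid-log phase, were collected by fast filtration, frozen and lysed cryogenically. Membrane-bound and soluble material were separated, and SRP72-bound material was pulled down from the soluble fraction by the tag on SRP72. Footprints of about 30 nt were made with RNase I, and RNA was broken to about 40 nt. Strains were BY4741 carrying SRP72-TAP, W303, and the prt1-1 mutant CY2522, the last pair at 25 °C or after a shift to 37 °C for 1 h. Cycloheximide (CHX) in the culture was 100 µg/mL at harvest, and lysates for RNA were incubated with CHX or puromycin.

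The labels describe 30 samples, and 24 libraries were used. The 6 monosome samples are not analysed here, so the monosome comparisons planned before the data were examined were not run. The planned fit over 5 untreated groups became a fit over 3 (soluble, membrane and SRP72-bound polysomes, 2 replicates each). In the RNA table, the BY4741 columns that name no drug were taken as the CHX lysate by elimination, since the other BY4741 columns name puromycin.

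The deposited count values are raw reads per open reading frame, per the file headers, with no normalization stated. Bowtie, TopHat, CASAVA, cutadapt 1.3 and the sacCer3 genome are named per the submitters' processing notes. How reads mapping to several places were treated, and whether counting used strand, is not given in the sources used here, so near-identical paralogs and overlapping genes are reported as uncertain. The authors' deposited enrichments are log2 ratios of DESeq2-scaled reads, per the file headers. They were compared with the counts as a check: over 4987 open reading frames the authors' log2 membrane enrichment equals the ratio of counts plus 0.824 (SD 0.0136), and over 4908 the SRP enrichment equals it plus 1.70 (SD 0.0207). The authors' class of each gene and the positions of signals, first signal and signal-to-stop lengths in codons were taken as deposited by the authors.

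Each count table held 5904 open reading frames and 3 lines with no name, which were dropped. Of these frames 5902 matched the RefSeq table of locus tags, and 4877 carry a name in the authors' file. Depth in M counts was 34.662 and 25.752 for soluble, 34.44 and 24.113 for membrane and 31.544 and 20.155 for SRP72-bound polysomes. From CHX culture it was 16.613 for soluble and 16.058 for membrane ribosomes, and 21.513 for soluble and for SRP72-bound polysomes. RNA of the CHX lysate had 27.0 (soluble), 24.686 (membrane) and 23.3 (SRP72-bound), and of the puromycin lysate 27.435, 34.3 and 15.57. At 25 °C W303 had 11.362 (soluble) and 3.139 (membrane) and prt1-1 11.4 and 8.109; at 37 °C they had 8.4 and 5.183, and 12.462 and 6.693. The 10 largest genes took 5.22% to 19.4% of a library. With 2 libraries per fraction the common biological coefficient of variation was 0.0805.

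Replicated footprints were fitted in R 4.3.3 with edgeR 4.0.16: TMM scaling (factors 1.60 and 1.56 for soluble, 0.96 and 1.02 for membrane, 0.61 and 0.67 for SRP72-bound), filterByExpr (minimum count 10, total 15), and the quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, for 5393 genes and 3 residual degrees of freedom. Membrane against soluble and SRP72-bound against soluble polysomes were planned. SRP72-bound against membrane polysomes was added after both had been seen. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and with an estimated correlation, on log2 CPM with a prior count of 2, where a list had 3 or more measured members. Adjustment ran over the lists of a comparison, and for fixed lists whose counts are printed, those adjusted over the list alone are given where they differ.

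The 20 fixed lists were written before the data were examined: ER lumen folding factors; ER translocon, signal peptidase and oligosaccharyltransferase; cell wall proteins with GPI anchors or secreted; vacuolar hydrolases; plasma membrane transporters; ER membrane lipid enzymes; Golgi and ER glycosyltransferases; p24 and cargo receptors; membrane subunits of the vacuolar ATPase (these 9 form the secretory lists). The others were tail-anchored proteins, mitochondrial matrix enzymes, mitochondrial carriers and inner membrane proteins, the mitochondrial genome (8 genes, too few measured in footprints for a list test), single-copy cytosolic ribosomal proteins, glycolysis and fermentation, cytosolic chaperones, nucleolar assembly factors, amino acid biosynthesis, heat shock genes, and SRP with its receptor. Ribosomal proteins, glycolysis and chaperones form the cytosolic lists. Of 179 secretory-list genes 142 are in the authors' classes of signal sequence or transmembrane genes, and of 24 tail-anchored genes 22 are in the authors' tail-anchored class. Of 403 list entries 1 (PPA1, a name shared by several genes) found no match. It had first been matched to a wrong gene, and this was corrected after values were seen. The authors' classes, predictions of SRP dependence, and groups of direct SRP binding and prerecruitment were used as deposited.

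For single libraries the value is the log2 ratio of TMM-scaled CPM with a pseudocount of 0.5, for genes with at least 50 counts over the libraries compared, computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Figures used matplotlib 3.10.9. Gene intervals cover Poisson counting error, shares have exact binomial 95% intervals, and list medians have order-statistic intervals and a percentile among 10000 random lists of the same size drawn from 20 expression bins. A gene with 0 counts in one library is given as at least N-fold lower, with a floor of 3 counts.

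Named genes in replicated comparisons were the 5 largest increases and 5 largest decreases with adjusted p under 0.05, a mean of at least 50 CPM and no overlap between groups. In single libraries they were the 4 highest and 4 lowest with at least 200 counts. The 2 members with the highest mean CPM of each list described were added, and SRP72, PRT1, HAC1, SEC61 and KAR2 were always named. Other genes are said to have been chosen after their values were seen.

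Alternatives fixed before the data were examined were relative log expression factors, scaling to the cytosolic lists, no filter, the DESeq2 1.42.0 Wald test, a fit over the compared groups alone, the replicate number as a block, and leaving out each replicate. For single libraries they were total counts, cytosolic scaling, at least 200 counts or 1 count, and a pseudocount of 5. The pipeline was tested on simulated data. In the edgeR fit, a true log2 change of 1 was called in 100% of genes in both comparisons. One of 0.5 was called in 78.6% for membrane and 70.3% for SRP72-bound polysomes. In the same order, a change of −1 was called in 100% and 94.9%, and one of −0.5 in 70.6% and 62.1%. Of unchanged genes 0.12% and 0.26% were called. Most simulated genes were unchanged (5079 of 5279 for membrane), so these rates do not cover scaling errors where many genes change, as in these data. In single libraries, list shifts of 0.5, 2 and −1 came back as 0.497, 2.02 and −1.04.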

Results

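Budding yeast ribosomes were sampled in 3 places to ask which messages are read free in the cytosol, at membranes, and while held by the signal recognition particle (SRP), which binds signal sequences and brings ribosomes to the endoplasmic reticulum (ER). Counts from 24 libraries were used, 10 of ribosome footprints and 14 of poly(A) RNA. BY4741 cells with a tandem affinity tag on the SRP subunit SRP72 supplied soluble, membrane-bound and SRP72-bound polysomes, with 2 libraries per fraction and no drug before harvest. Another 4 footprint libraries, from cells given cycloheximide (CHX, which stalls elongating ribosomes) at harvest, were single libraries, as were all RNA libraries. Monosome samples were not analysed here. Footprint libraries held 16.058 to 34.662 M counts and RNA libraries 3.139 to 34.3 M, over 5904 open reading frames. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples. Replicates differed beyond sampling noise, with chi-square per degree of freedom of 15.3 for soluble, 38.2 for membrane and 89.6 for SRP72-bound polysomes. The median chi-square over genes was 4.95, 8.13 and 6.96 times its expected value, in the same order. Pearson's r of log2 CPM (counts scaled to library size) was nevertheless 0.9946 or more.

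Membrane polysomes were compared with soluble polysomes to ask which proteins are made at membranes. SPF1, an ER P5-type ATPase (YEL031W, chromosome V 90258 to 93905 in R64), stood highest, at 2374 ± 355 CPM on membranes and 14.1 ± 2.19 CPM in the soluble fraction (mean ± SD, n = 2). Its log2 fold change was 7.40 ± 0.27 (± SE here and below; 169-fold; adjusted p = 5.26e-08, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, as for all adjusted p-values of genes here). PEP1, the sorting receptor for vacuolar hydrolases, ROT2, the catalytic subunit of glucosidase II, and KRE5, needed for β-1,6-glucan, rose by 7.38 ± 0.16, 7.33 and 7.24 ± 0.15. The uncharacterised CSS1 rose by 7.26 ± 0.19. The plasma membrane proton pump PMA1 rose by 7.06 ± 0.26, the ER chaperone KAR2 by 6.67 ± 0.17 (adjusted p = 1.23e-08, edgeR) and the translocation channel SEC61 by 6.18 ± 0.17, from 27.3 ± 1.52 to 1975 ± 368 CPM.

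At the other end, footprints of ribosomal protein genes fell, with RPL41B lowest at −1.47 ± 0.14 (adjusted p = 2.5e-05, edgeR). RPL41A, RPS6A, RPL42A and RPL42B followed at −1.12, −1.02, −0.99 and −0.96, but all 5 belong to near-identical pairs, so reads cannot be assigned securely to one copy. The single-copy ribosomal protein RPL3 was at −0.34 ± 0.11 (adjusted p = 0.0207, edgeR), a call that ended with cytosolic scaling (−0.10), with the replicate number as a block and whichever library was left out. All 20 single-copy ribosomal protein genes were called lower, at a median of −0.61 (17 and −0.38 with cytosolic scaling).

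Across 5393 tested genes, 1844 were called higher on membranes, 1268 of them by over 2-fold, and 1882 lower (49.5% of calls higher). Scaling to cytosolic genes, in place of the trimmed mean of M values (TMM), moved the all-gene median from −0.07 to 0.17 and made this 2299 higher and 722 lower (76.1% higher). Of 178 measured members of the secretory lists, 168 rose, 164 of them by over 2-fold, 2 fell and 8 did not pass, at a median of 5.61 and with the same numbers adjusted over the list alone. The camera test gave adjusted p = 4.17e-34 for this set with a preset correlation, and adjusted p = 0.33 with an estimated correlation. The estimated correlation rests on 3 residual degrees of freedom, so a list can miss the threshold with it even where every member rose. The absence of such a call, here and below, does not argue against a shift.

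All members rose among ER lumen folding factors (20 of 20, median 5.89), plasma membrane transporters (32 of 32, median 5.2), ER membrane lipid enzymes (25 of 25, 5.68), Golgi and ER glycosyltransferases (25 of 25, 5.93), p24 and cargo receptors (13 of 13, 4.74) and vacuolar hydrolases (10 of 10, 6.40). Among these were the disulfide isomerase PDI1 (6.003 ± 0.163), the drug pump PDR5 (5.22 ± 0.17), the sterol enzymes ERG11 (6.37 ± 0.18) and ERG25 (5.54 ± 0.17), and the O-mannosyltransferase PMT1 (6.80). The nucleotide sugar carrier VRG4 (5.25 ± 0.19), the p24 proteins ERV25 (4.07 ± 0.13) and EMP24 (3.24 ± 0.13), and the vacuolar enzymes APE3 (6.37 ± 0.15) and PRC1 (5.86 ± 0.14) also rose. Camera called each of these 6 lists with the preset correlation and none with an estimated one (adjusted p = 0.33). Over all 19 lists tested, 12 passed with the preset and 0 with the estimated correlation, 1 at an unadjusted p under 0.05.

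Some secretory genes stayed with soluble polysomes. In the list of translocon, signal peptidase and oligosaccharyltransferase subunits, 14 of 16 rose (median 5.41), including the second channel SSH1 (6.33 ± 0.18). The exceptions, named after their values were seen, were the oligosaccharyltransferase subunit OST2 (−0.10 ± 0.15, adjusted p = 0.559, edgeR) and the signal peptidase subunit SPC1 (−0.37 ± 0.18, adjusted p = 0.0999, though called lower in a fit of these fractions alone). In the vacuolar ATPase membrane subunits 6 of 7 rose (median 2.67), VPH1 by 3.70 ± 0.12 and the proteolipid VMA3 by 1.52 ± 0.17, whereas the small subunit VMA9 did not (−0.28 ± 0.18, called lower in that fit). Cell wall proteins divided, with 23 of 30 higher (median 5.50, ECM33 at 5.99 ± 0.20) but the mannoproteins CCW12 (−0.58 ± 0.12, adjusted p = 0.00337, edgeR) and CWP2 (−0.63 ± 0.12) lower, the call of CCW12 ending without soluble replicate 2 (−0.46). With an estimated correlation camera called none of these 3 lists (adjusted p = 0.347).

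Proteins inserted after translation behaved differently: 23 of 24 tail-anchored genes fell (median −0.51; camera adjusted p = 0.312 with an estimated correlation), but 11 at a median of −0.27 with cytosolic scaling. Among them were the translocon subunit SSS1 (−0.63 ± 0.08) and the ER contact-site protein SCS2 (−0.38 ± 0.10), which lost its call with that scaling (−0.15) and without soluble replicate 2 (−0.29). Mitochondrial lists were mixed. Carriers and inner membrane proteins had 17 of 30 higher and 9 lower (median 0.90; adjusted p = 0.719 with an estimated correlation), led by the ADP/ATP carrier PET9 (3.23 ± 0.16) and the oxaloacetate carrier OAC1 (2.56 ± 0.10). Matrix enzymes had 12 of 24 higher and 1 lower (median 0.28), and camera did not call them (adjusted p = 0.0724; 0.776 estimated) except with the preset correlation and cytosolic scaling (0.0238). The matrix chaperone SSC1 rose by 0.42 ± 0.11, a call lost without soluble replicate 1 (0.35), while ILV5 of branched-chain amino acid synthesis was at 0.01 ± 0.12. Of the mitochondrially encoded genes, which had few footprints, ATP6 rose by 4.60 ± 0.48.

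Few genes of the other cytosolic lists were called. Glycolytic genes had 2 higher and 3 lower of 18 (0 and 2 adjusted over the list alone; median −0.08), chaperones 1 and 3 of 22 (0 and 2; −0.03), and amino acid enzymes 3 and 2 of 21 (−0.07). Scaling to cytosolic genes turned these 3 medians to 0.16, 0.20 and 0.16. Nucleolar assembly factors had 8 higher and 2 lower of 25 (6 and 0 over the list alone), and their median of −0.00 became 0.23 with that scaling. Within them the processing factor RRP5 rose by 0.70 ± 0.09. Heat shock genes had 7 higher and 6 lower of 18 (median 0.19). The cytosolic lists together had 26 lower of 60 (median −0.19, 0.04 with cytosolic scaling; camera adjusted p = 0.741 with an estimated correlation).

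Genes of the particle itself were near 0 or lower. SRP72 was at 0.19 ± 0.15 (adjusted p = 0.278, edgeR), but was called higher with cytosolic scaling (0.43) and in a fit of these fractions alone (0.20). SRP54, the GTPase that binds signals, was at −0.30 (adjusted p = 0.0593) and was called lower in the latter fit, and SRP68 was at −0.02. Of the 8 subunits of SRP and its receptor only the membrane-spanning β subunit of the receptor (YKL154W, named after its value was seen) rose (4.88 ± 0.20), while SRP21 (−0.68 ± 0.13), SRP14 (−0.63 ± 0.08) and SEC65 (−0.46 ± 0.08), likewise named after their values were seen, fell (list median −0.16, 0.07 with cytosolic scaling; adjusted p = 0.895 estimated). Translation initiation factor PRT1 (0.09 ± 0.10, but called higher at 0.32 with cytosolic scaling) and the unfolded protein regulator HAC1 (−0.20 ± 0.13) did not pass.

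In the authors' classes, 72 of 74 genes with a signal sequence and a transmembrane segment rose (median 5.55), 471 of 541 with transmembrane segments alone (4.25), 148 of 181 with a signal sequence alone (4.69) and 37 of 48 with a GPI anchor (4.56). With estimated correlations these classes did not pass camera (adjusted p = 0.163 to 0.165). The cytonuclear class had 1550 lower and 526 higher of 3419 (median −0.21, 0.02 with cytosolic scaling). Camera compares a class with all other tested genes, so a pass need not mean that the genes of that class fell. The cytonuclear class was the only one to pass camera with an estimated correlation (adjusted p = 0.0121). The authors' tail-anchored class (2 higher and 40 lower of 52, median −0.51), mitochondrial class (279 and 163 of 536, 0.34) and exceptions (346 and 90 of 590, 0.64) did not (adjusted p = 0.163, 0.165 and 0.175). Of genes predicted by the authors as SRP dependent 350 of 399 were higher (median 4.67), and of SRP independent ones 250 of 280 (5.08), a difference that was not tested.

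**Figure D1:**
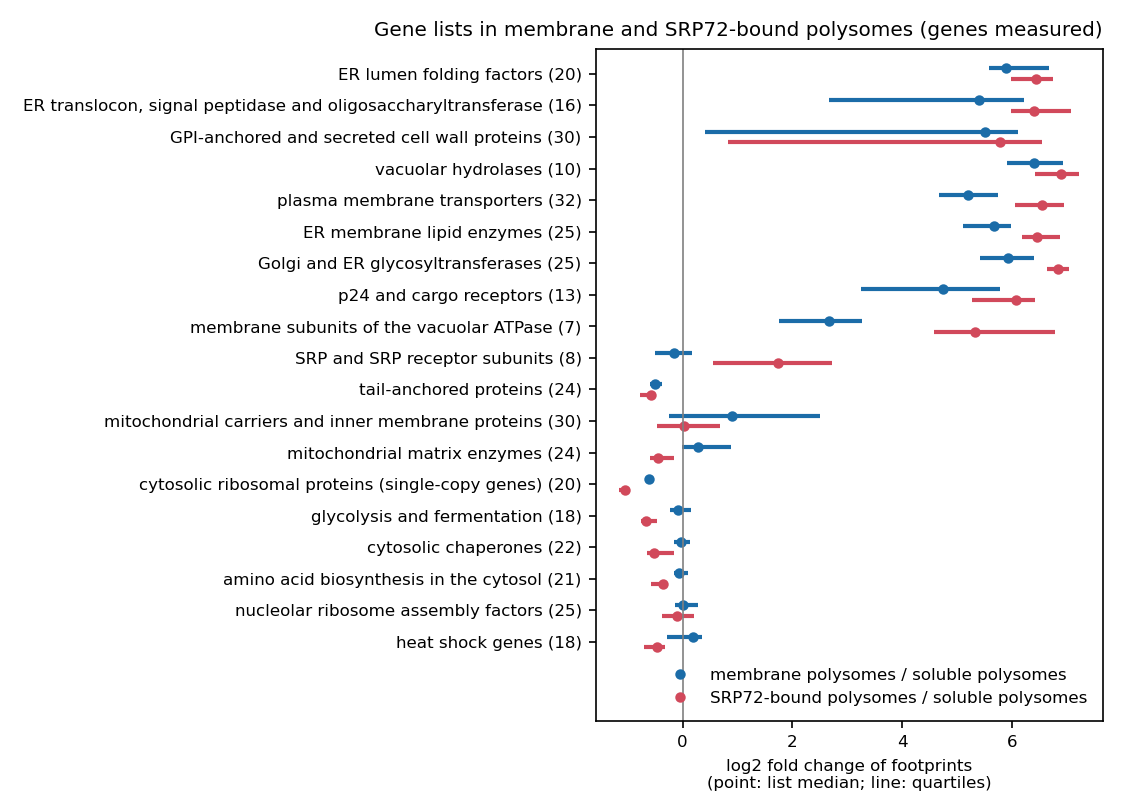
Log2 fold change of ribosome footprints (horizontal axis) for 19 gene lists (vertical axis), membrane against soluble polysomes in blue and SRP72-bound against soluble polysomes in red. Points are list medians, lines run between quartiles, n = 2 libraries per fraction; lists of cytosolic and tail-anchored genes lie below 0 in red but above it when scaled to cytosolic genes, apart from ribosomal proteins.

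SRP72-bound polysomes were compared with the same soluble polysomes to ask which ribosomes the particle holds before they reach membranes. PER33, a membrane protein of the ER and nuclear pores (YLR064W, chromosome XII 265456 to 266277 in R64), was highest, at a log2 fold change of 8.12 ± 0.27 (279-fold; adjusted p = 1.82e-08, edgeR). The lipid phosphatase LPP1 rose by 8.08 ± 0.22, GPI19 of GPI anchor synthesis by 8.03 ± 0.21, and the plasma membrane proteins YRO2 and MRH1 by 8.02 ± 0.17 and 7.95 ± 0.24. OST2, flat on membranes, rose by 6.99 ± 0.19 here (adjusted p = 6.97e-09), from 66.7 to 8474 CPM. SEC62, a translocon subunit for completed chains, rose by 7.38 ± 0.18, SEC61 by 6.71 ± 0.18 and KAR2 by 7.52 ± 0.18 (adjusted p = 5.13e-09, edgeR).

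The tagged subunit's own message was higher as well. SRP72 (YPL210C, chromosome XVI 154290 to 156212 in R64) rose by 3.002 ± 0.161 (8.01-fold), from 69.4 ± 1.74 to 555.7 ± 134 CPM (n = 2, adjusted p = 5.01e-07, edgeR). As the pulldown used the tag on SRP72, capture of nascent SRP72 by its own tag cannot be told apart from capture by the particle. No pulldown from untagged cells was among the samples. SRP54 rose by 2.46 ± 0.13 (adjusted p = 4.68e-07). Genes of this family named after their values were seen were SRP21 (2.63 ± 0.14), SEC65 (0.68 ± 0.08), the α and β subunits of the receptor (YDR292C, 1.03 ± 0.09; YKL154W, 6.02 ± 0.21), and SRP14, which fell (−0.83 ± 0.08) but did not pass with cytosolic scaling (−0.14). SRP68 was at 0.20 ± 0.08 (adjusted p = 0.055, edgeR) and was called higher with cytosolic scaling (0.89), relative log expression factors or DESeq2. Altogether 6 of 8 rose and 1 fell (7 and 1 over the list alone; median 1.74), and camera called the list only with the preset correlation (adjusted p = 0.0337; 0.398 estimated) and not with cytosolic scaling (0.109).

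Lowest were the ribosomal protein genes RPL29 (−1.37 ± 0.11, adjusted p = 7.79e-06, edgeR), RPL42B (−1.34), RPS17A (−1.30), RPL42A (−1.25) and RPL26B (−1.24 ± 0.09), of which all but RPL29 have a near-identical copy. All 20 single-copy ribosomal protein genes fell (median −1.05, camera adjusted p = 0.302 with an estimated correlation), RPL3 by −0.90 ± 0.11, although RPL3 did not pass with cytosolic scaling (−0.21). PRT1 fell by −0.49 ± 0.10 (adjusted p = 0.00182, edgeR), but with cytosolic scaling it stood at 0.20 and did not pass. HAC1 did not pass (−0.32 ± 0.15), except without SRP72-bound replicate 2 (−0.495).

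The test called 2105 genes higher, 1390 of them by over 2-fold, and 2098 lower (50.1% of calls higher). With cytosolic scaling the all-gene median moved from −0.04 to 0.65, and 3563 genes were higher and 272 lower (92.9% higher), so that 482 genes called lower became called higher. Of 178 secretory-list genes, 172 rose, 169 by over 2-fold, and 2 fell (median 6.49, the same over the list alone; camera adjusted p = 3.36e-31, or 0.302 with an estimated correlation). Among the lists incomplete on membranes, 16 of 16 translocon, signal peptidase and oligosaccharyltransferase genes (median 6.41) and 7 of 7 vacuolar ATPase subunits (5.33) rose. Examples are SPC1 (5.60), VMA9 (3.20 ± 0.19), VMA3 (5.33 ± 0.20) and the proteolipid VMA11 (6.78 ± 0.21).

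Every member also rose among folding factors (20, median 6.44), transporters (32, 6.55), lipid enzymes (25, 6.46), glycosyltransferases (25, 6.84), p24 and cargo receptors (13, 6.07) and hydrolases (10, 6.89). Named members were PDI1 (6.44 ± 0.17), PMA1 (7.15 ± 0.27), PDR5 (6.02 ± 0.18), TSC13 of fatty acid elongation (6.60 ± 0.20), ERG11 (6.82 ± 0.18), VRG4 (6.88 ± 0.21), the glucan synthesis gene KRE6 (7.03 ± 0.13), ERV29 (6.07 ± 0.18), ERV25 (5.53 ± 0.14), APE3 (6.80 ± 0.15) and PRC1 (6.38 ± 0.15). Cell wall proteins again divided, with 24 of 30 higher (median 5.79; GAS1 6.90 ± 0.17, ECM33 6.50 ± 0.21) and CCW12 and CWP2, named here after their values were seen, lower (−0.85 and −0.81), calls that ended with cytosolic scaling (−0.16 and −0.12). Camera called these 9 lists with the preset correlation and none with an estimated one (adjusted p = 0.302 or 0.303, 0.395 for cell wall proteins). Of all 19 lists 17 passed with the preset and 0 with the estimated correlation, 1 at an unadjusted p under 0.05.

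Tail-anchored genes were again lower, 22 of 24 at a median of −0.57, although cytosolic scaling turned this to 0.11 (camera adjusted p = 0.302 with an estimated correlation). The exceptions were TLG2, a syntaxin-like SNARE of endosomes, which rose by 3.56 ± 0.13 (adjusted p = 3.02e-08, edgeR), and UFE1, a syntaxin of the ER named after its value was seen, which did not pass (−0.10 ± 0.10, adjusted p = 0.394) but was called higher with cytosolic scaling (0.59). The signal-to-stop length of TLG2 is 79 codons, against a median of 25.5 in the authors' tail-anchored class. TLG2 therefore need not stand for tail-anchored proteins in general. Matrix enzymes fell for 17 of 24, at a median of −0.45 that became 0.24 with cytosolic scaling (0.458 estimated). Among them ILV5 (−0.54 ± 0.12) and SSC1 (−0.29 ± 0.11) fell, and under that scaling SSC1 rose (0.40) while ILV5 did not pass (0.14). The call of SSC1 also ended without either soluble replicate (−0.38 and −0.21) or SRP72-bound replicate 2 (−0.22). The F1-ATPase subunit ATP2 (0.52) and the mitochondrial elongation factor TUF1 (1.96 ± 0.18), named after their values were seen, rose. Carriers and inner membrane proteins had 8 higher and 11 lower of 30 and no call by camera (adjusted p = 0.914; 0.969 estimated), which leaned down although the median was 0.02 and the mean 0.37. PET9 rose by 0.78 ± 0.15 and the succinate dehydrogenase anchor SDH3 by 2.94 ± 0.13.

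Other cytosolic and nucleolar lists had medians below 0 that scaling to cytosolic genes turned above it, unlike that of ribosomal proteins (−0.36 after that scaling). Glycolytic genes had 14 of 18 lower (median −0.66, 0.03 after that scaling), chaperones 16 of 22 (−0.51, 0.18), amino acid enzymes 18 of 21 (−0.36, 0.32), heat shock genes 14 of 18 (−0.46, 0.22) and nucleolar factors 11 of 25, with 6 higher (10 lower over the list alone; −0.10, 0.58). With estimated correlations camera called none of these (adjusted p = 0.457, 0.458, 0.458, 0.45 and 0.697). Genes that rose within them included RRP5 (1.21 ± 0.09), the rRNA processing factor UTP10 (1.06 ± 0.11) and the chaperonin subunits TCP1 and CCT3 (0.34 and 0.33). The aromatic pathway enzyme ARO1 (0.35) rose as well. All of these but RRP5 were named after their values were seen. Among heat shock genes 3 were called higher. Without soluble replicate 1 the calls of TCP1, CCT3 and ARO1 ended (0.28, 0.22 and 0.21), and that of ARO1 also without either SRP72-bound replicate (0.33 and 0.36). The cytosolic lists together had 50 of 60 lower and 2 higher (median −0.69; camera adjusted p = 0.398 with an estimated correlation).

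Of the authors' transmembrane class 516 of 541 rose (median 6.08), of signal sequence genes 154 of 181 (5.52), of genes with both 73 of 74 (6.22) and of GPI-anchored genes 38 of 48 (5.15). Of predicted SRP-dependent genes 377 of 399 rose (6.19), and of independent ones 258 of 280 (6.004), a difference that was not tested. None of these passed camera with an estimated correlation (adjusted p = 0.165, or 0.176 for GPI anchors). The authors' exceptions had 390 of 590 higher (0.97; 0.171 estimated), whereas cytonuclear genes had 1723 of 3419 lower (−0.29, 0.40 with cytosolic scaling; adjusted p = 0.0164 estimated). Mitochondrial genes (212 higher and 210 lower of 536, median −0.03) and tail-anchored genes (38 of 52 lower, −0.55) turned to 0.65 and 0.13 with cytosolic scaling. The authors' groups of direct SRP binding (227 of 230 higher, 6.52) and prerecruitment (478 of 484, 6.31) were drawn from these samples and are not independent evidence.

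Membrane and SRP72-bound fold changes share their soluble controls. Across 5393 genes they correlated at r = 0.923 with covariance 4.34, where 20 simulations without any effect gave 0.483 (highest 0.537) and 0.0261. Signs matched for 83.4% of genes (66.5% simulated). Called higher in both were 1588 genes (0.05 simulated, 719.75 for independent lists), lower in both 1573 (0.05; 732.14), and over 2-fold higher in both 1113 (0; 326.82). With a separate soluble library for each comparison, tried after these values were seen, r was 0.906 or 0.918 over 5403 genes, depending on which library served which, with covariance 4.32 or 4.37. Then 1448 or 1505 genes were called higher in both and 1215 or 1279 lower in both.

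**Figure D2:**
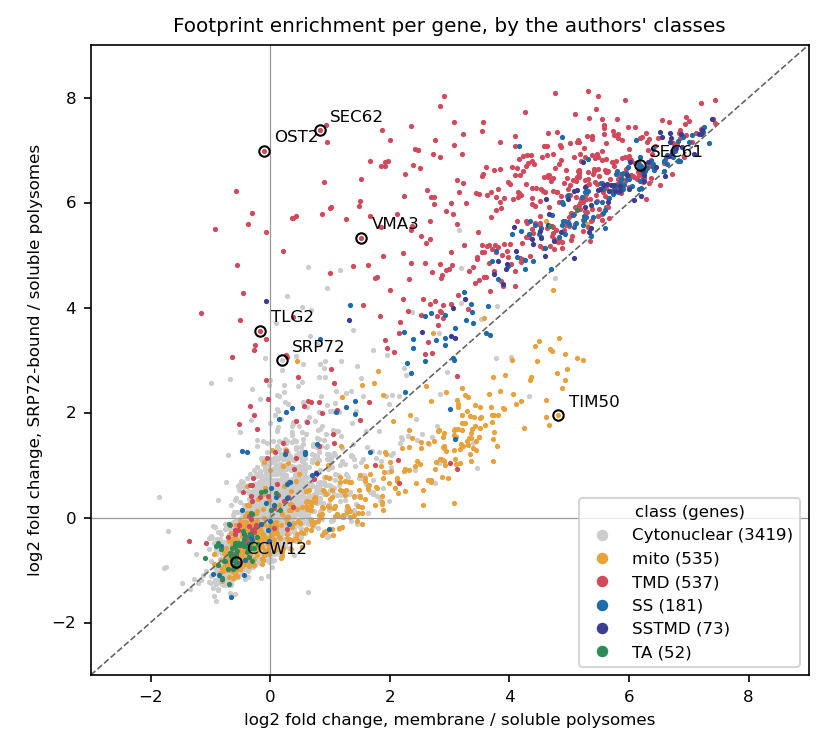
Log2 fold change of footprints in membrane polysomes (horizontal axis) and in SRP72-bound polysomes (vertical axis), each against soluble polysomes. Each point is 1 of 4797 genes with counts in every fraction, without the authors' 590 exceptions, coloured by the authors' class (TMD transmembrane, SS signal sequence, SSTMD both, TA tail-anchored, mito mitochondrial), fold changes come from 2 libraries per fraction, the dashed line marks equal values, and OST2 and TLG2 lie near 0 on membranes but at 6.99 and 3.56 with SRP72.

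All remaining comparisons in these Results rest on 1 library per condition: no replicate check was possible and no p-values are given. Intervals cover counting error only, and reads amplified by PCR without molecular identifiers are not independent molecules. Shares are of secretory-list genes with a ratio over 2-fold, with exact 95% intervals, and list medians are ranked among 10000 random lists of matched expression.

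CHX added to the culture asks whether footprints keep their place when elongation is stalled at harvest. Membrane material with CHX was ribosomes, compared with soluble ribosomes, whereas that without the drug was polysomes. Differences in level between these membrane comparisons therefore cannot be assigned to the drug. Membrane ribosomes against soluble ribosomes had SEC61 at 4.93, PMA1 at 4.95, PDI1 at 4.33 and KAR2 at 2.93 in log2 ratio. KRE5 (5.48 [5.11, 5.90]), the tricalbin TCB2 (5.44) and the vacuolar glutathione pump YCF1 (5.41) were highest, with PHO11 at 5.31 but nearly identical to PHO12; ACF2 (−0.96), SHR5 (−0.78), SAS2 (−0.68) and NTR2 (−0.58) were lowest. Of 176 secretory genes 163 were over 2-fold higher (92.6% [87.7, 96.0]; median 3.47, percentile 100). Folding factors stood at a median of 4.03, lipid enzymes at 4.14, vacuolar ATPase subunits at 1.96, tail-anchored genes at −0.11, and matrix enzymes at 0.37. CCW12 (−0.07), SRP72 (−0.00) and PRT1 (−0.03) lay near 0, on either side of it by scaling, and HAC1 at −0.30. The all-gene median of −0.05 became −0.19 by total counts.

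SRP72-bound polysomes from CHX culture had SPF1 (7.90 [7.77, 8.04]), the vacuolar transporter YBT1 (7.87), PMA1 (7.49), KAR2 (7.47), SEC61 (7.18), SRP54 (4.47) and SRP72 (2.70) above soluble polysomes. COS1 (8.71 [6.81, 14.61], 1 soluble count) and ENA5 (8.04 [6.49, 11.41], 2 soluble counts) ranked above them but belong to near-identical families. RPL41B (−2.31), RPL41A (−2.15), RPL29 (−2.05) and the dynein light chain DYN2 (−2.01) were lowest. Secretory genes over 2-fold higher were 173 of 176 (98.3% [95.1, 99.7]; median 6.55, percentile 100), with vacuolar ATPase subunits at 5.18. Tail-anchored genes stood at −0.75, ribosomal proteins at −1.33, CCW12 at −0.98, PRT1 at −0.26 (0.389 with cytosolic scaling) and HAC1 at 0.27 (−0.673 by total counts). The all-gene median was −0.06, −0.998 by total counts and 0.59 with cytosolic scaling.

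Poly(A) RNA of CHX-treated and puromycin-treated lysates asks whether messages stay with membranes and SRP once nascent chains are released, since puromycin ends translation early. In the CHX lysate, membrane RNA was enriched for SEC61 (3.43 [3.40, 3.47]), KAR2 (3.55), PDI1 (3.46), PMA1 (3.20) and ERG11 (3.56). The vacuolar peptidases APE3 (3.97) and CPS1 (3.90), the sterol reductase ERG4 (3.81) and the tricalbin TCB3 (3.77) were highest. MSL1, of the U2 snRNP, was at least 67.4-fold lower (0 against 288 counts), followed by FAR7 (−6.02 [−8.53, −4.68], 3 membrane counts), MIY2 (−5.18) and SHU1 (−3.19). Secretory genes over 2-fold higher were 158 of 179 (88.3% [82.6, 92.6]; median 2.97, percentile 100).

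By list, medians in the CHX-lysate membrane were 3.21 for folding factors, 3.05 for translocon and modification enzymes, 3.39 for hydrolases, 3.22 for lipid enzymes, 3.26 for glycosyltransferases, 2.59 for p24 proteins, 2.28 for cell wall proteins, 2.21 for transporters and 1.62 for vacuolar ATPase subunits. Messages of the mitochondrial genome stood at 2.15, with 8 of 8 over 2-fold higher, and mitochondrial carriers at 0.42 (PET9 1.80). Glycolytic genes (−0.45), PRT1 (−0.46) and HAC1 (−0.59) were below 0. Tail-anchored genes (−0.09), ribosomal proteins (−0.27) and CCW12 (−0.16) were near it and turned to 0.249, 0.0647 and 0.184 with cytosolic scaling, and SRP72 (0.01) to −0.374 by total counts. The all-gene median of −0.01 became −0.39 by total counts and 0.33 with cytosolic scaling.

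Membrane enrichment was lower in the puromycin lysate but not absent. SEC61 stood at 0.98 [0.96, 1.01], a change of −2.45 [−2.49, −2.40] from the CHX lysate, KAR2 at 1.92 (−1.63), PDI1 at 1.19 (−2.27), PMA1 at 1.36 (−1.84), ERG11 at 1.55 (−2.01) and VMA3 at 0.09 (−1.26), the level of VMA3 being −0.0187 by total counts. Secretory genes over 2-fold higher were 88 of 179 (49.2% [41.6, 56.7]; median 0.99). Their ratios changed by a median of −1.69 [−1.77, −1.56], below all 10000 random lists, and 152 of 179 were over 2-fold lower. Changes were −2.17 for lipid enzymes, −2.09 for p24 proteins, −2.03 for translocon genes, −1.71 for folding factors, −1.70 for glycosyltransferases, −1.18 for cell wall proteins and −1.55 for the mitochondrial genome, against 0.27 for tail-anchored and 0.21 for ribosomal protein genes. Since messages of the mitochondrial genome fell as well (interval −2.01 to −0.63), a lower recovery of membranes in this single library was not excluded. HAC1 (0.28) and CCW12 (0.35) changed little, as did SRP72 (−0.27, but 0.00609 by total counts) and PRT1 (0.05, but −0.104 with cytosolic scaling). The meiotic genes SPR1 (2.57) and HOP2 (2.48), with PEX9 (2.48) and MLG1 (2.40), were highest in the puromycin lysate; YOL159C-A (−3.67), JEN1 (−3.19), ECI1 (−2.90) and FMP48 (−2.68) were lowest. Of the 8 genes at the ends of the change, 7 had 3 counts or fewer in a library and are not named.

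In SRP72-bound RNA of the CHX lysate, SEC61 (5.35 [5.31, 5.38]), KAR2 (5.47), PDI1 (5.35), ERG11 (5.75), PMA1 (4.79) and VMA3 (3.83) were enriched over soluble RNA. YLR342W-A (6.35), CPS1 (6.27), ILM1 (6.18) and ERG4 (6.16) were highest, and BTT1 of the nascent polypeptide-associated complex (−3.31), MTC3 (−2.76), ADD37 (−2.53) and TDA2 (−2.45) lowest. Secretory genes over 2-fold higher were 169 of 179 (94.4% [90.0, 97.3]; median 5.01, percentile 100). Medians were 5.36 for lipid enzymes and for glycosyltransferases, 5.34 for translocon genes, 5.27 for folding factors and 4.16 for vacuolar ATPase subunits. They were −1.92 for ribosomal proteins, −1.98 for glycolytic genes and −0.85 for tail-anchored genes, the last becoming 0.793 with cytosolic scaling. CCW12 stood at −1.85, PRT1 at −1.22 (0.426 with cytosolic scaling), the tagged SRP72 at 0.66 (−0.588 by total counts) and HAC1 at 0.17 (−1.07 by total counts). The all-gene median of −0.05 became −1.29 by total counts and 1.60 with cytosolic scaling.

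This capture was lower in the puromycin lysate as well. SEC61 stood at 2.06 in log2 ratio (change −3.29 [−3.33, −3.24]), PDI1 at 2.42 (−2.94), KAR2 at 3.48 (−1.99), PMA1 at 3.32 (−1.47), ERG11 at 3.11 (−2.64) and VMA3 at −0.41 (−4.24), a level that was 0.973 with cytosolic scaling. Secretory genes over 2-fold higher were still 147 of 178 (82.6% [76.2, 87.9]; median 2.23). Their median change was −2.42 [−2.56, −2.21], or −1.46 by total counts, with 166 over 2-fold lower. Messages of the mitochondrial genome had a higher median, 2.72, so enrichment of this size was not particular to secretory messages. Changes were −3.49 for p24 proteins, −3.39 for translocon genes, −3.22 for vacuolar ATPase subunits, −3.09 for lipid enzymes, −2.42 for glycosyltransferases, −2.33 for folding factors and −1.49 for cell wall proteins. By total counts these falls were smaller, from −2.53 for p24 proteins to −0.53 for cell wall proteins. The mitochondrial genome changed by 0.20 (−0.0569 with cytosolic scaling, 1.17 by total counts). In the puromycin lysate COX3 (4.48), YOR394C-A (4.37), BI2 (4.36) and BI3 (4.23) were highest, BI2 and BI3 lying within the same mitochondrial gene as COB. MZM1, YOR111W, YHR138C and PET191 were at least 89.5-, 85.6-, 66.1- and 60.4-fold lower, with 0 SRP72-bound counts. In this library 9 open reading frames had 0 counts despite a median of at least 200 in the other RNA libraries, the most of any. Loss from this single library therefore cannot be told apart from depletion. HAC1 stood at 0.76, SRP72 at 0.04 (−0.239 by total counts), and PRT1 (−0.62) and CCW12 (−1.34) turned to 0.764 and 0.0447 with cytosolic scaling. The all-gene median of this change was −0.05, 0.91 by total counts and −0.32 with cytosolic scaling; 6 of the 8 genes at its ends had 3 counts or fewer in a library and are not named.

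**Figure D3:**
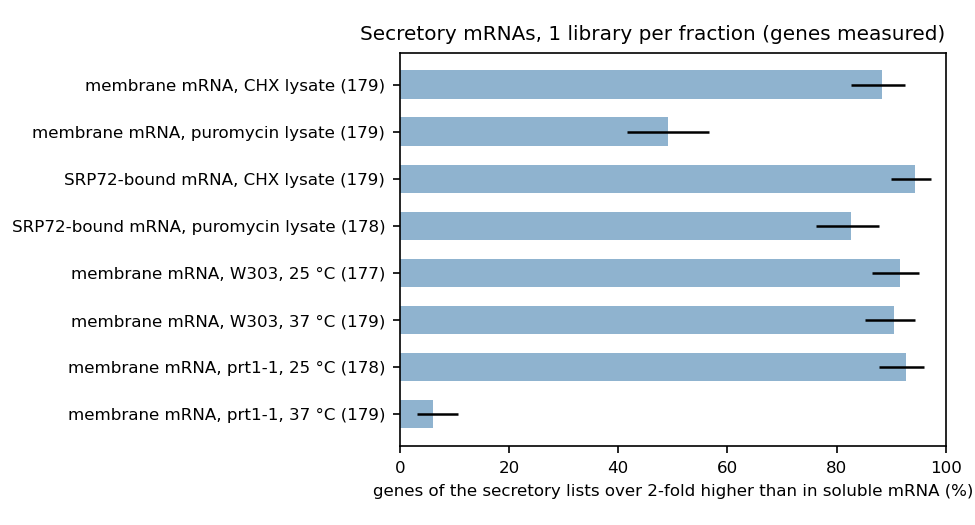
Share of secretory-list genes (percent, horizontal axis) with a poly(A) RNA ratio over 2-fold in membrane-bound or SRP72-bound against soluble RNA, for each lysate and each strain and temperature (vertical axis). Bars are shares from 1 library per fraction and lines are exact 95% binomial intervals, from 6.15% in prt1-1 at 37 °C to 94.4% in SRP72-bound RNA of the CHX lysate.

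The strains W303 and prt1-1, a temperature-sensitive mutant of an eIF3 subunit, ask whether message placement at membranes needs initiation. In W303 the membrane enrichment of secretory messages was similar at 25 °C and after 1 h at 37 °C. SEC61 stood at 4.39 and 3.94, KAR2 at 3.52 and 3.57, PMA1 at 3.87 and 3.60 and PDI1 at 3.68 and 4.44. Secretory genes over 2-fold higher were 162 of 177 (91.5% [86.4, 95.2]; median 3.43) and 162 of 179 (90.5% [85.2, 94.4]; median 3.57), and the median change was 0.05 [−0.03, 0.16], but −0.306 by total counts and −0.324 with cytosolic scaling. Highest were YLR285C-A (6.19 and 5.84), with PHS1 of fatty acid elongation (5.23 and 5.17), YLR342W-A and the near-identical PHO12 at 25 °C (5.78 and 5.46), and LOH1 and ERG25 at 37 °C (5.32 and 5.04). Lowest at 25 °C were NAT5 (−1.92), RPL40B (−1.89), RPS28B (−1.85) and ATP17 (−1.83), and at 37 °C RIP1 (−1.48), YCL042W, YDR249C and SMD1 (−1.43, −1.40 and −1.39), of which RPL40B and RPS28B have near-identical copies and YCL042W and SMD1 overlap other genes. All-gene medians moved from −0.05 to 0.83 at 25 °C and from −0.10 to 0.40 at 37 °C with cytosolic scaling.

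The prt1-1 strain lost this enrichment at 37 °C. SEC61 went from 3.22 at 25 °C to 0.17 at 37 °C, a change of −3.06 [−3.18, −2.93], KAR2 from 2.60 to 0.66 (−1.94), PDI1 from 3.73 to 0.01 (−3.72) and PMA1 from 3.03 to −0.52 (−3.55). The 37 °C levels of SEC61 and PDI1 were −0.0844 and −0.244 with cytosolic scaling. SSH1 (−5.43) and ERG11 (−4.84) changed more and VMA3 (−2.29) less. CCW12 changed by −0.13, and SRP72 (0.27) and HAC1 (0.20) turned to −0.955 and −1.03 with cytosolic scaling. Over 2-fold higher were 165 of 178 secretory genes at 25 °C (92.7% [87.8, 96.1]; median 2.88) and 11 of 179 at 37 °C (6.15% [3.11, 10.7]; median −0.16 [−0.26, −0.06]). The median change was −2.96 [−3.17, −2.73], with 163 of 179 over 2-fold lower, and the difference from the W303 change was −2.94 [−3.19, −2.75].

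The loss in prt1-1 reached every secretory list: hydrolases −3.46, translocon genes −3.36, lipid enzymes −3.32, glycosyltransferases −3.22, folding factors −3.10, p24 proteins −2.91, vacuolar ATPase subunits −2.62, transporters −2.38 and cell wall proteins −2.02. Messages of the mitochondrial genome kept their place, at 1.79 and 2.36 (8 of 8 over 2-fold higher at 37 °C; change 0.77 [−0.28, 1.79], −0.455 with cytosolic scaling), with COX3 (4.52), COX2 (4.21) and the overlapping Q0255 (3.53) highest at 37 °C, then AIM20 (3.41). The ratios of glycolytic genes changed by 1.64, of chaperones by 1.41 and of amino acid enzymes by 1.08, but by 0.415, 0.182 and −0.144 with cytosolic scaling, which moved the all-gene median of this change from −0.02 to −1.25. TDH3 (1.45), PRT1 (1.21) and RPL3 (0.58) became 0.223, −0.0133 and −0.646 with that scaling. Lowest at 37 °C were YOR111W and YPL257W (at least 92.3- and 37.9-fold lower), FDH1 (−7.40 [−13.29, −5.49], 1 count) and TIR2 (−5.99 [−8.49, −4.65], 3 counts). At 25 °C PHO12 (5.41, near-identical to PHO11), YLR285C-A (5.02), YLR342W-A (4.96) and YNL058C (4.92) were highest, and COX14 (−4.17), ELP6 (−3.61), YER010C (−3.23) and SPC1 (−2.89) lowest.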

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

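Medians of heat shock genes had opposite signs in the strains, though not with cytosolic scaling, by a comparison of soluble RNA at 37 °C with 25 °C that was not among those planned. Their median log2 ratio over 18 genes was 2.169 [1.53, 3.25] in W303, with 16 over 2-fold higher, and −1.335 [−2.04, 1.60] in prt1-1, with 6 higher and 10 lower. Each value rests on 1 library per temperature, and the difference was not tested. The all-gene median of the prt1-1 ratios was 0.23, and scaling to cytosolic genes moved it to 2.05 and the heat shock median to 0.488, so the direction in prt1-1 depends on the scaling.

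The genes of this list parted in prt1-1, and those named here were chosen after their values were seen. The small heat shock proteins HSP26 (6.22 in W303 and 2.76 in prt1-1) and HSP42 (3.40 and 3.03), the membrane-stabilising HSP12 (6.15 and 4.70), the disaggregase HSP104 (2.48 and 0.59) and the inducible Hsp70 gene SSA4 (4.46 and 0.97) were higher at 37 °C in both strains. The cochaperone STI1 (1.24 and −3.03), the mitochondrial chaperonin HSP60 (1.46 and −2.46) and SSA1 (2.16 and −4.50, near-identical to SSA2) were higher in W303 and lower in prt1-1, also under total counts and cytosolic scaling. The Hsp90 gene HSP82, which shares reads with HSC82, stood at 3.25 and −1.78, the latter becoming 0.045 with cytosolic scaling.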

How the results depend on the processing

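Scaling to the cytosolic lists changed both counts of calls and directions. It left 722 genes lower on membranes, gave 3563 higher and 272 lower on SRP72-bound against soluble polysomes, and 3163 higher (1113 by over 2-fold) and 314 lower against membrane polysomes. It reversed ILV5 (0.138), SSC1 (0.397), PRT1 (0.197) and UFE1 (0.588) on SRP72-bound polysomes, of which SSC1 and UFE1 passed, PRT1 (0.426) in SRP72-bound RNA of the CHX lysate and CCW12 (0.0447) in that of the puromycin lysate. In soluble RNA of prt1-1 at 37 °C it reversed ribosomal protein genes (0.771), heat shock genes (0.488) and HSP82 (0.045), and in the prt1-1 membrane change amino acid enzymes (−0.144) and PRT1 (−0.0133). It ended the calls of SCS2 and RPL3 on membranes and of RPL3, CCW12, CWP2 and SRP14 with SRP72, and made calls of SRP72 (0.431) and PRT1 (0.324) on membranes and of SRP68 (0.888) with SRP72. Among lists under the preset correlation it made a call of matrix enzymes on membranes and ended those of matrix enzymes, amino acid enzymes and SRP subunits with SRP72. By its construction it holds cytosolic lists near 0 and raises all other genes where those lists fell. An estimated correlation in camera called 0 fixed lists in each comparison, with 1 of 19 at an unadjusted p under 0.05 for membrane, 1 for SRP72-bound against soluble and 0 for SRP72-bound against membrane polysomes. It was estimated with 3 residual degrees of freedom. Even ER lumen folding factors, with 20 of 20 higher on membranes, had an unadjusted p of 0.0677 by camera with it. Lack of a call with it therefore does not argue against a shift of a list, and the cause was not tested. In single libraries, shares of secretory genes over 2-fold higher after puromycin became 63.1% on membranes and 91.6% with SRP72 under cytosolic scaling. The secretory puromycin change was −1.42 by total counts and −1.85 by cytosolic scaling on membranes, and −1.46 and −2.69 with SRP72. The temperature change in W303 was −0.306 and −0.324, that of prt1-1 −4.19 by cytosolic scaling, and their difference −2.69 and −3.79.

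Leaving out 1 library at a time assumes that the lone sample left in a fraction varies like the other groups. It gave 1719 to 1799 genes higher, 1497 to 1639 lower and 1237 to 1288 over 2-fold higher on membranes; 1950 to 2026, 1834 to 1942 and 1368 to 1424 with SRP72; and 1323 to 1586, 1155 to 1426 and 553 to 722 for SRP72-bound against membrane polysomes. The membrane call of RPL3 ended whichever of the 4 libraries was left out (−0.372 to −0.297). Without soluble replicate 1 the calls of SSC1 on membranes (0.351) and of SSC1 (−0.375), TCP1 (0.275), CCT3 (0.223) and ARO1 (0.208) with SRP72 ended. Without soluble replicate 2 those of CCW12 (−0.463) and SCS2 (−0.293) on membranes and SSC1 (−0.212) with SRP72 ended. ARO1 also lost its call without SRP72-bound replicate 1 (0.334) or 2 (0.363), and SSC1 without replicate 2 (−0.224), where HAC1 gained one (−0.495). In SRP72-bound against membrane polysomes SEC61 lost its call without membrane replicate 2 (0.354), and PMA1 gained one without SRP72-bound replicate 1 (0.354) but stood at −0.234 without replicate 2.

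With the replicate block 1897 genes were higher and 2008 lower on membranes, 2145 and 2174 with SRP72, and 1674 and 1643 for SRP72-bound against membrane polysomes. Of the genes and list tests reported here the block ended the call of RPL3 on membranes (−0.336) and changed no other call. Over all genes it kept 3718 of 3726 calls on membranes, 4197 of 4203 with SRP72 and 3126 of 3151 between these, and gained others. Counts within lists moved with it, to 10 of 18 glycolytic genes lower in SRP72-bound against membrane polysomes. Deviations of same-numbered libraries correlated at 0.325, 0.12 and 0.087 between fractions, with 2 libraries in each, so they are taken to share only a number.

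Relative log expression factors gave 1900 higher and 1708 lower on membranes, 2202 and 1927 with SRP72; DESeq2 gave 1851 and 1464, 2127 and 1785; no filter gave 1855 and 1866, 2109 and 2128; fits over the compared groups alone gave 1824 and 1838, 2080 and 2144. The last made calls of SRP54, SRP72, SPC1 and VMA9 on membranes (−0.30, 0.197, −0.371 and −0.273). Relative log expression factors ended that of SSC1 (−0.234) with SRP72 and, like DESeq2, made one of SRP68 (0.257). Among genes and lists of the replicated comparisons under all alternatives, 1617 values stayed on their side of the threshold, 30 of them with the sign turned (20 by cytosolic scaling), 92 lost their call (65 of them under an estimated correlation in camera), 12 gained one and 4 reversed. In single libraries 1401 values stayed within their intervals and 7 reversed. Another 472 moved, 266 by cytosolic scaling, 197 by total counts and 9 with a pseudocount of 5. Minimums of 200 counts or 1 count moved none of 376. The value of a single gene does not depend on the minimum, so only shares and list medians could have moved. No monosome comparison was run, and apart from the construction of the cytosolic scaling the cause was not tested. Depth limits W303 at 25 °C most, with 3.139 M membrane counts.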

Other observations

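SRP72-bound polysomes were also compared directly with membrane polysomes, a comparison and a choice of 4 signal-position bins made after the planned contrasts were seen, as were the tests on SRP subunits and on prt1-1 below. OST2 was 136-fold higher on SRP72-bound polysomes (log2 fold change 7.09 ± 0.19, n = 2 per fraction; adjusted p = 6e-07, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The uncharacterised YGL194C-A (6.79 ± 0.22), SEC62 (6.56 ± 0.18), the vacuolar ATPase assembly factor PKR1 (6.53 ± 0.18) and the Golgi transport protein SFT2 (6.21 ± 0.17) followed. The vacuolar proteolipids VMA11 (4.81) and VMA3 (3.81), with VMA16 (4.03), VMA9 (3.47) and SPC1 (5.97), the last 3 named after their values were seen, were also higher. TLG2 (3.72), ERV29 (3.05) and TSC13 (2.92) followed, whereas KAR2 (0.85) and SEC61 (0.54, not called without membrane replicate 2, at 0.354) rose little and PMA1 did not pass (0.09, adjusted p = 0.717). Without SRP72-bound replicate 1 PMA1 was called higher (0.354), and without replicate 2 it stood at −0.234 and did not pass. In the SRP family SRP54 (2.76), SRP72 (2.81), and, chosen after the values were seen, SRP21 (3.31) and the receptor's β subunit YKL154W (1.13) rose.

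Mitochondrial messages lay on the other side of that comparison. The NADH dehydrogenase NDE1 fell by −2.90, the import receptor TIM50 by −2.86 ± 0.14, cytochrome c peroxidase CCP1 by −2.64 ± 0.10, the lactate dehydrogenase DLD1 by −2.52 ± 0.13 and the mitochondrial transcription factor MTF1 by −2.52. PET9 fell by −2.45 and OAC1 by −2.33. Matrix enzymes had 23 of 24 lower (median −0.74) and carriers and inner membrane proteins 22 of 30 (−0.79), against 7 of 7 higher for vacuolar ATPase subunits (3.47), 29 of 32 for plasma membrane transporters (1.24), 13 of 16 for translocon genes (0.83) and 7 of 8 for SRP and its receptor (1.13). Adjusted over the list alone, 30 transporters and 14 translocon genes were higher, as were 3 carriers in place of 2, and 1 SRP gene was lower. Cytosolic lists were lower too, 52 of 60 together (−0.48) and 18 of 18 for glycolysis (−0.53), but cytosolic scaling left 4 and 1 of these and 13 matrix enzymes (median −0.29). Fewer glycolytic genes were also called lower with the replicate number as a block. Of the authors' predicted SRP-dependent genes 321 of 399 were higher (1.05), 209 by over 2-fold, and of independent ones 184 of 280 (0.52), 56 by over 2-fold, a difference that was not tested. Camera called the mitochondrial, vacuolar ATPase, transporter, translocon and SRP lists with the preset correlation but gave adjusted p = 0.34 for each with an estimated one. Of all genes 1604 were higher and 1547 lower (50.9% of calls higher). Cytosolic scaling moved the all-gene median from −0.01 to 0.44, made this 3163 and 314 (91.0%), and turned the authors' mitochondrial class from −0.43 to 0.02.

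Heat changed soluble messages of W303 in other groups as well, with 1 library per temperature and no test. Ribosomal protein genes were lower at 37 °C (median −1.63, or −0.994 with cytosolic scaling) and nucleolar assembly factors too (−1.46, or −0.82), while ER folding factors stood at 0.64 (1.27) and KAR2 at 1.83 (2.46). In prt1-1 nucleolar factors (−2.15), glycolytic genes (−2.34) and chaperones (−2.03) were lower, but stood at −0.328, −0.518 and −0.212 with cytosolic scaling, where ribosomal proteins went from −1.05 to 0.771. Glycolytic genes, chaperones and ribosomal proteins are the genes scaled to. Cytosolic scaling holds them near 0 together by construction, so it cannot decide whether they fell. Secretory genes were higher in the soluble RNA (median 1.04, or 2.86 with that scaling), vacuolar hydrolases among them at 2.31 (4.13). In the membrane fraction of W303 the ratios of HSP26 (−4.43), HSP12 (−4.31), TMA10 (−3.89) and GPM2 (−3.06) moved down most with heat and those of HSP30 (2.75), LOH1 (2.09), EMP46 (1.93) and DIA3 (1.86, overlapping another gene) up.

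Genes with a shorter stretch from signal to stop codon tended to be higher on SRP72-bound than on membrane polysomes. Over 796 genes of the authors' signal and transmembrane classes, the length from signal to stop codon and the SRP72-bound against membrane fold change had Spearman's rho −0.4073 [−0.476, −0.336], and −0.29 [−0.366, −0.21] given coding length, and this may reflect chains that are released before the ribosome docks. The trend was not monotonic. The median was 1.91 below 100 codons (45 genes, 55.6% called over 2-fold higher) and 2.44 from 100 to 200 (123 genes, 74.8%). It was 1.08 from 200 to 400 (230 genes) and 0.58 above (398 genes). Coding length itself had rho −0.3139, and 0.1001 [0.00574, 0.19] given the signal-to-stop length. Short coding length alone as the cause needs a negative value given the signal-to-stop length, so it is argued against for these 796 genes. At a fixed signal-to-stop length, coding length varies only with signal position, and the −0.29 given coding length has the same limit. Coding length together with signal position therefore cannot be told apart from signal-to-stop length. At 50 CPM or more 46.15% of genes were called over 2-fold higher, against 43.1% below. These shares cannot decide whether few footprints are the cause. A call needs an adjusted p under 0.05 (edgeR), which noisy genes seldom reach, and the CPM came from the same membrane and SRP72-bound libraries. No experiment here changed signal position, so an effect of signal-to-stop length remains a hypothesis.

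Of the 5 untagged SRP subunits, SRP21, SRP54 and SEC65 had more footprints in the SRP72 pulldown. Capture through the message cannot be told apart from capture through the nascent chain. With puromycin, in 1 library per lysate, their RNA ratios changed by −2.57, −0.85 and −1.12, and the median of −1.12 lay within the −2.79 to 0.60 of random lists. SRP14 and SRP68, which were not higher in the pulldown, changed by 0.37 and 0.50. Assembly of subunits during their translation may be one source and was not tested.

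Loss of membrane enrichment in prt1-1 at 37 °C may follow from failed initiation, since PRT1 encodes a subunit of eIF3. Messages of the mitochondrial genome changed by 0.7719 (−0.455 with cytosolic scaling, where secretory genes changed by −4.19) and stayed with membranes. A loss of mitochondria as large as the fall of secretory messages is therefore argued against, by these few genes in 1 library per condition. Whether poly(A) libraries recover these messages evenly was not tested. These messages do not report on the ER, so failed separation of ER membranes cannot be excluded by them and was not tested. Scaling is argued against by a secretory median of −2.96 or lower under all 3 scalings, and sparse libraries by −3.003 over 160 genes with at least 200 counts in each library. The shift of temperature alone gave 0.04997 in W303, or −0.324 with cytosolic scaling. With 1 library per condition the strain, its growth and its handling stay confounded.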
